A study of Mus musculus with 37 samples.

How the data were processed

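The samples were mammary glands of female C57BL/6 mice that entered the study at 9 weeks of age and were followed for 6 weeks. The 4 groups were mice fed ad libitum (AL), mice fed ad libitum with a running wheel (AL+EX), mice under calorie restriction (CR) and mice under calorie restriction with a running wheel (CR+EX). Restricted mice got 70% of the calories of AL mice, per the labels. RNA came from the pooled left and right thoracic glands of each animal, and each animal had 1 biotin-labelled Affymetrix oligonucleotide array, 37 in all. The table held 22690 probe sets and no column of any other sample.

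Each value was an Affymetrix signal intensity, as deposited on a linear scale. The submitters' processing notes name GCOS version 1, and the signal algorithm, detection calls and filters are not given in the sources used here. The authors had scaled the arrays: the mean after trimming 2% of the values at each end lay between 500.165 and 500.23 on every array, so no further scaling was applied. Signals were used as log2(signal + 16), which damps the noise of dim probe sets. Array data carry no counts, so the number of arrays per group limits the precision. The highest signal of an array lay between 20690 and 84279.

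Gene names came from the platform's own table, checked through Entrez gene IDs. There were 20380 probe sets naming 1 gene, 691 naming several, 1555 naming none and 64 control probe sets, and 29 probe sets had an Entrez ID without a match and kept the platform's symbol. For each of the 12393 genes the probe set with the highest mean over all arrays was used. The 25% of genes with the lowest mean, below 6.71 on the log2 scale (a signal of 88.7), were left out, which left 9294 genes. No genome positions were used.

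Comparisons were made with limma 3.58.1 in R 4.3.3. Group means were fitted to all 37 arrays (33 residual degrees of freedom), with empirical Bayes variances that follow the mean signal, and 9 contrasts were tested: the 6 pairs of groups, the effect of CR averaged over both exercise states, the effect of the wheel averaged over both diets, and the interaction. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each contrast, and genes with an adjusted p under 0.05 were called. Errors given with ± are standard errors from that fit unless SD is written. The median residual SD was 0.339 on the log2 scale.

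There were 45 gene lists, and 44 had 5 or more tested genes (the list of lymph node stroma had too few). Each was tested against all other genes by the competitive test camera in limma with a preset correlation between genes of 0.01, and again with an estimated correlation. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. In 20 simulated draws a list shifted by 0.5 on the log2 scale was called in 100% of draws by both. Every gene of that list got the shift and no smaller shift was simulated, so the power for smaller differences is not known. In simulated arrays with no shifted list, the test with the preset correlation called a mean of 8.3 lists and up to 22, against 0 with an estimated correlation. A permutation test of the difference in list means was therefore added after the data were seen: exact over all 92378 or 48620 regroupings for pairs of groups, and over 100000 random draws for the other contrasts, two-sided and adjusted over the 44 lists. The same test was also run for the averaged CR effect within runs of animal numbers, with 20000 draws.

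The groups, contrasts, tests, gene lists, filters, most alternative settings and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls past the threshold in each contrast, up to 2 risen and 2 fallen members of each list, the member with the smallest p of a called list with no member past the threshold, the 3 smallest p of a contrast without calls, and Lep, Adipoq, Fasn, Scd1, Igf1, Mest and Sfrp5 in every contrast. Genes outside the rule are named as such.

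The animal numbers in the titles were cut after every 24 numbers. This left 4 runs with arrays, 2 to 22, 26 to 48, 50 to 70 and 122 to 144, with 8, 11, 10 and 8 arrays. The numbers themselves show a wide gap only between 70 and 122. Each run holds all 4 groups, and the labels do not say whether a run was a batch. Within each run the numbers rise in the order AL, AL+EX, CR and CR+EX. The place of an animal in its run therefore goes with its group, and a run block or permutation within runs cannot separate them. The labels do not say whether animals were handled in that order. With each gene centred on its mean in each group, arrays of different groups resembled each other more within a run (median correlation 0.276) than between runs (-0.0876). The report therefore also gives counts of genes or of lists with the run as a block for each contrast. Some values per run are given for the averaged CR contrast. Other alternatives were 2 other offsets, quantile normalization, median centring, other filters, other uses of the probe sets, no variance trend, array weights, only the groups compared, the mean of a cell type list as a covariate and each array left out. Of these, 3 were added after the data were seen: the run block with the B lymphocyte covariate, and fits without the arrays high in B lymphocyte genes or in the Gapdh 3' to 5' ratio.

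The fit was tested on simulated data with 200 changed genes and the residual spread of these arrays. For the averaged CR contrast, 82.8% of genes changed 1.5-fold and 96% of genes changed 2-fold were recovered, with a mean of 6.6 false calls. For the averaged wheel contrast the values were 83.2%, 98.9% and 4.7. For AL+EX against AL they were 54.8%, 88.3% and 4.1, for CR+EX against CR 55%, 90.6% and 3, and for the interaction 23.2%, 71.7% and 1. For CR against AL they were 59.1%, 90.3% and 25.6, for CR+EX against AL 58.8%, 90.7% and 23.2, for CR+EX against AL+EX 56.8%, 89.5% and 7.3, and for CR against AL+EX 53.3%, 88.5% and 4.5.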

Results

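The data are gene signals from whole mammary glands of 37 mice, with 10 AL, 9 AL+EX, 9 CR and 9 CR+EX animals and 9294 genes tested. The trimmed mean signal was near 500.2 on every array, and the correlation of log2 values between arrays ran from 0.869 to 0.984. Samples differed in their content of lymphoid genes: 22 arrays had a mean over the B lymphocyte genes of 6.60 to 7.12 on the log2 scale and 15 arrays had 8.10 to 10.4, with no array between. Those 15 arrays were 4 AL, 4 AL+EX, 4 CR and 3 CR+EX animals. They included all 8 arrays of the fourth run of animal numbers. The first principal component held 22.1% of the variance and followed the B lymphocyte mean (r = 0.957 across arrays). The second held 12.7% and the third 9.4%, and the third did not follow that mean (r = -0.074). The run of animal numbers explained shares of 0.721, 0.265 and 0.871 of components 1 to 3. The group explained shares of 0.025, 0.345 and 0.017.

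The averaged CR contrast asks what restriction did to the gland regardless of the wheel, with 18 restricted against 19 unrestricted animals. Of genes of lipid synthesis, 10 of 20 in the lipogenesis list and 6 of 19 in the cholesterol synthesis list were called higher and none lower. The second list lost its camera call with an estimated correlation (adjusted p = 0.073 with an estimated correlation). Elovl6, which elongates fatty acids, rose 2.01-fold (log2 difference 1.01 ± 0.12, adjusted p = 1.9e-06), and Me1, the malic enzyme that supplies NADPH for fat synthesis, rose 2.03-fold (1.02 ± 0.14, adjusted p = 5.9e-06). Genes of the circadian clock moved in both directions: the repressor Nr1d1 fell by 1.74 ± 0.23 and the output factor Dbp fell by 1.34 ± 0.18. At the same time Nfil3, a repressor that opposes Dbp at its target sites, rose by 1.19 ± 0.14 (adjusted p = 5.3e-06 for Nr1d1 and Dbp and 1.2e-06 for Nfil3). Lep, the gene of the satiety hormone leptin, fell by 1.39 ± 0.38 (2.62-fold, adjusted p = 0.018). It did not pass without the 5 arrays with a Gapdh 3' to 5' ratio above 2 (-0.95, adjusted p = 0.14) or without the 15 arrays high in B lymphocyte genes (-1.43, adjusted p = 0.056). These 6 genes, called on the same arrays, kept their direction in all 4 runs of animal numbers. For Lep the fall was far larger in run 1 than in the other runs, and run 1 holds 4 of the 5 arrays with the high ratio.

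In that contrast 813 genes passed the threshold, 389 higher and 424 lower. Of these, 156 differed by over 1.5-fold and 731 (89.9%) had the same direction in all 4 runs. The genes were called on these same arrays, which raises that share, and the share among uncalled genes was not taken. With the run as a block, 1743 genes passed (802 higher, 941 lower), among them all of the 813. The split between directions moved with the scaling, to 491 higher and 180 lower after median centring and to 425 and 313 after quantile normalization. Without the 15 arrays high in B lymphocyte genes 497 genes passed, and without the 5 arrays with a Gapdh 3' to 5' ratio above 2 there were 622.

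**Figure D1:**
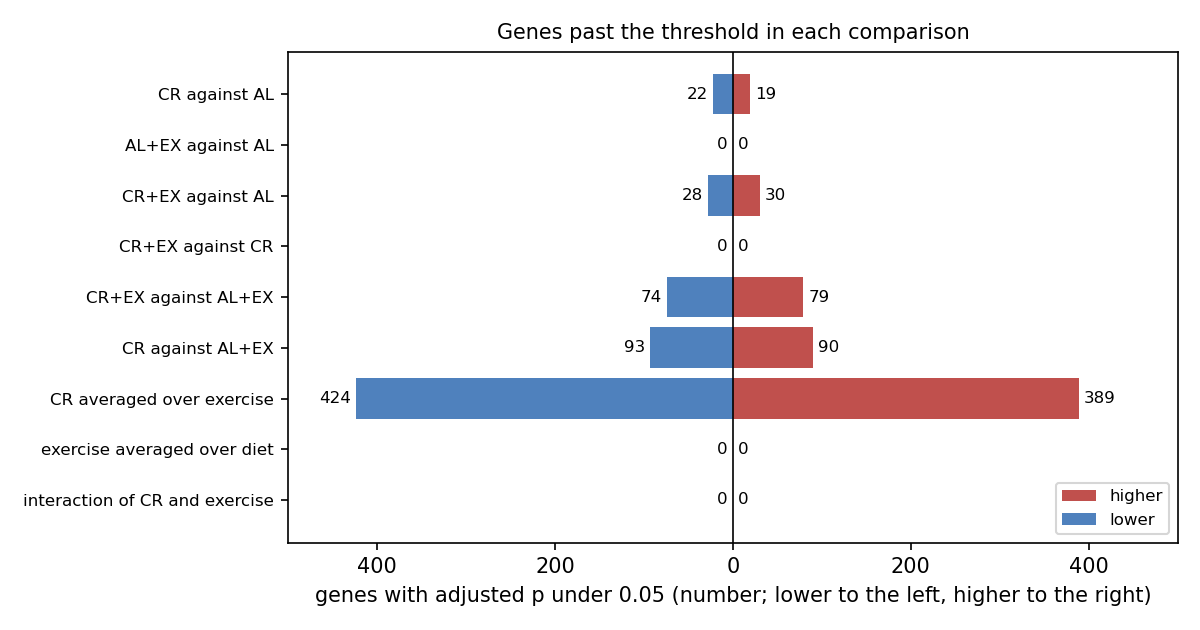
Number of genes with an adjusted p under 0.05 in each of the 9 contrasts, with lower genes to the left of 0 and higher genes to the right (horizontal axis: number of genes). The averaged CR contrast has 389 higher and 424 lower genes, and the 4 contrasts without calls are those of the wheel within a diet, the wheel averaged over diet and the interaction.

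Of 20 tested genes in the lipogenesis list, 10 rose and none fell over all genes tested, and 11 rose when adjusted over the list alone. The list's median was 0.40 (camera adjusted p = 3.6e-11, adjusted p = 0.049 with an estimated correlation, permutation adjusted p = 0.00022). With an estimated correlation and the run as a block the call was lost (adjusted p = 0.12). The medians by run were 0.15, 0.36, 0.55 and 0.43. Fasn, the fatty acid synthase (0.25 ± 0.13, adjusted p = 0.23), and Scd1, the main desaturase (-0.17 ± 0.17, adjusted p = 0.61), did not pass. Cholesterol synthesis had 6 of 19 genes higher and none lower, and 9 when adjusted over the list alone. The list median was 0.25 (camera adjusted p = 8.2e-06, adjusted p = 0.073 with an estimated correlation, permutation adjusted p = 0.00029). Its largest rises were Fdps, which makes farnesyl diphosphate (0.93 ± 0.18, a gene whose 1 other probe set moved the opposite way), and the mevalonate pathway kinase Pmvk (0.87 ± 0.13). In the list of NADPH and pentose phosphate genes 3 of 9 rose, and 5 when adjusted over the list alone (median 0.23, camera adjusted p = 6.8e-05, adjusted p = 0.073 with an estimated correlation, permutation adjusted p = 0.00022). It was led by Me1 and by the epimerase Rpe (0.51 ± 0.11), which had 1 of its 2 other probe sets in the same direction.

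**Figure D2:**
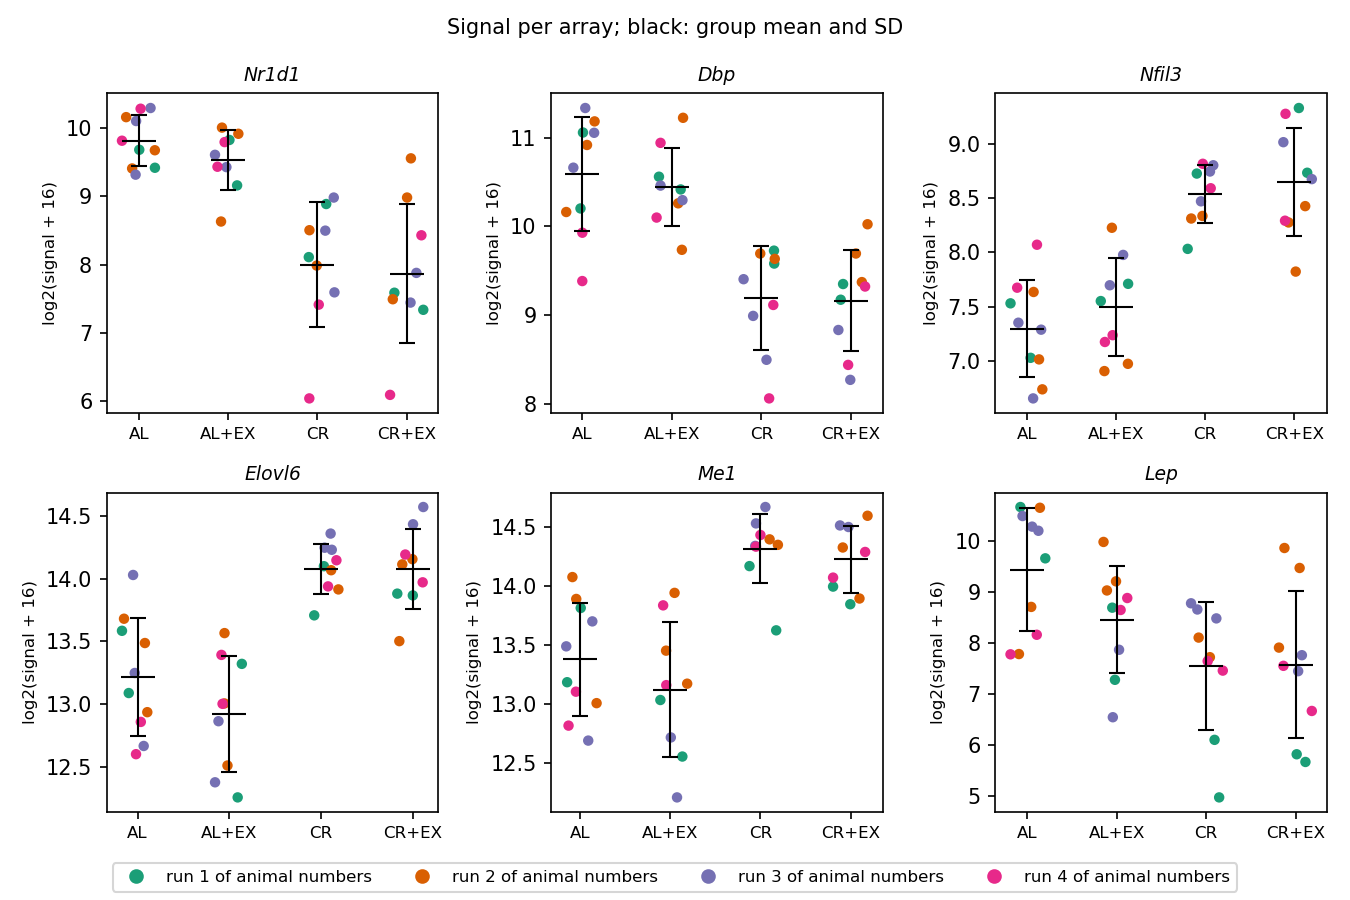
Signal of 6 genes on each array as log2(signal + 16), by group and coloured by run of animal numbers, with the group mean and SD in black. Nr1d1, Dbp and Lep lie lower and Nfil3, Elovl6 and Me1 higher in the CR and CR+EX groups, with Nr1d1 at 9.81 in AL and 7.87 in CR+EX on average.

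In the circadian clock list 7 of 17 genes fell and 3 rose, with the same counts adjusted over the list alone. Camera gave an adjusted p of 0.045, which was lost with an estimated correlation (adjusted p = 0.51 with an estimated correlation). The permutation adjusted p of the list mean was 0.0041. Besides Nfil3, the core repressor Cry1 rose by 0.53 ± 0.16 and the core activator Arntl rose by 0.42 ± 0.13 (adjusted p = 0.036 and 0.034). Arntl was chosen after its values were seen. Insulin and IGF signalling had 4 higher and 2 lower of 25 genes, and 8 and 5 adjusted over the list alone (median 0.14, camera adjusted p = 0.045, adjusted p = 0.51 with an estimated correlation, permutation adjusted p = 0.044). The growth factor Igf1 (0.51 ± 0.14), the receptor substrate Irs1 (0.53 ± 0.12) and the IGF binding protein gene Igfbp2 (0.51 ± 0.17) rose. At the same time Tsc1, a brake on mTOR, fell by 0.38 ± 0.11, as did the kinase subunit gene Pik3ca, by 0.24 ± 0.07.

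Mitochondrial and fat cell lists had smaller differences in the list mean than the lipogenesis, cholesterol synthesis and NADPH lists. Like those of the clock and insulin lists, their camera calls were lost with an estimated correlation. In the TCA cycle list 4 of 21 genes rose, also 4 adjusted over the list alone (median 0.13, camera adjusted p = 5.7e-05, adjusted p = 0.51 with an estimated correlation, permutation adjusted p = 0.046). Dlat of pyruvate dehydrogenase rose by 0.58 ± 0.11 and pyruvate carboxylase, Pcx, by 0.56 ± 0.13. The respiratory chain had 3 of 36 genes higher by both counts, over all genes and adjusted over the list alone (adjusted p = 0.70 with an estimated correlation), led by cytochrome c, Cycs (0.31 ± 0.08). Adipocyte markers had 3 of 16 higher, 4 adjusted over the list alone (adjusted p = 0.51 with an estimated correlation), with the secreted proteins Retn (0.64 ± 0.19) and Rbp4 (0.49 ± 0.16). Adipoq did not pass (0.14 ± 0.11, adjusted p = 0.46). Lipolysis and lipid droplets had 2 of 12 higher, 4 adjusted over the list alone (adjusted p = 0.51 with an estimated correlation). The 2 were Abhd5, an activator of triglyceride lipase (0.50 ± 0.10), and G0s2, an inhibitor of the same enzyme (0.37 ± 0.11). Fatty acid oxidation had 2 of 19 higher, 3 adjusted over the list alone (adjusted p = 0.70 with an estimated correlation). The 2 were the peroxisomal Ehhadh (0.75 ± 0.18) and the uncoupling protein Ucp3 (0.34 ± 0.09).

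Among cell type lists, luminal epithelium had 3 of 24 genes lower and none higher by both counts, over all genes and adjusted over the list alone. Its median was -0.37 (camera adjusted p = 0.0010, adjusted p = 0.70 with an estimated correlation, permutation adjusted p = 0.21). By run the medians were -0.48, -0.37, -0.97 and 0.23, so the fourth run went the other way. The surface antigen Cd24a fell by 0.71 ± 0.15 and the secreted protein Wfdc2 fell by 0.67 ± 0.21. Collagens and matrix had 5 of 34 higher and 1 lower, 8 and 1 adjusted over the list alone (adjusted p = 0.70 with an estimated correlation). Among them were the collagen chaperone Serpinh1 (0.91 ± 0.23), Col15a1 (0.65 ± 0.21) and the lower P4ha2 (-0.43 ± 0.14). Mast cells had none of 6 past the threshold (adjusted p = 0.51 with an estimated correlation, permutation adjusted p = 0.046), and Cma1 was at 0.37 ± 0.15 (adjusted p = 0.11). Fibroblasts had 1 of 14 higher (Pcolce, 0.55 ± 0.16, adjusted p = 0.70 with an estimated correlation). The B lymphocyte list had a median of -0.41 with none of 11 genes past the threshold (camera adjusted p = 0.29), beside the uneven lymphoid content described above.

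The other lists were not called by camera. Single members passed in glycolysis (Pgam1 higher, Hk1 and Slc2a1 lower), the glucocorticoid and fasting response (Tsc22d3, Nr3c1 and Angptl4 higher, the last with its 1 other probe set the opposite way), adipose expansion (Lep), and milk proteins (Btn1a1 higher, with both other probe sets the opposite way). Others passed in hormone response (Stat5b lower), macrophages (Cd163 higher), nerve and Schwann cells (Pmp22 higher), red blood cells (Alas2 higher), interferon response (Usp18 lower), inflammation (Hp and Socs3 lower), immediate early genes (Ier3 and Junb lower), heat shock (Hspa4l higher), antioxidants (Prdx3 higher, Gclc lower), autophagy and lysosome (Gabarapl2 higher) and sirtuins and longevity (Nampt higher). Nr3c1 was chosen after its values were seen. No member passed in brown fat, basal epithelium, proliferation, skeletal muscle, T lymphocytes, plasma cells, neutrophils, endothelium, lymphatic endothelium, smooth muscle and pericytes, skin and hair, MHC class II presentation, ER stress or ribosomal proteins. Camera adjusted p-values of all lists not called lay between 0.055 (macrophages) and 0.77 (neutrophils).

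Some of these calls held in fewer than 80% of the alternative settings in which the gene was tested: P4ha2 (10 of 17), Socs3 (10 of 16), Igfbp2 (11 of 16), Tsc1 and Pik3ca (12 of 17 each), and Col15a1, Rbp4 and Angptl4 (13 of 17 each). Of 37 fits that left out 1 array, Igfbp2 lost its call in 26, Socs3 in 22, Rbp4 in 21, P4ha2 in 18, Col15a1 in 16, and Angptl4 in 9, while Tsc1 and Pik3ca kept theirs. Wfdc2 (21), Btn1a1 (16) and Cry1 (11) also lost theirs in more than 10 of these fits. With the mean of all probe sets of a gene in place of the brightest, the calls lost were those of Angptl4 (adjusted p = 0.76), Hk1 (0.38), Cycs (0.32), Tsc1 (0.30), Pik3ca (0.25), Atp5o (0.16), Rpe (0.14), Ctse (0.082) and Ucp3 (0.058). Atp5o, of the respiratory chain list, held its call in 12 of 17 settings and in every fit without 1 array.

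The largest rises past the threshold were Enpep, which cleaves angiotensin II (1.41 ± 0.24), Hcar2, the receptor for the ketone body beta-hydroxybutyrate (1.40 ± 0.26), Igfals, which holds IGF in the circulation (1.32 ± 0.27), the linker histone gene H1f10 (1.26 ± 0.25), Olfm1 (1.22 ± 0.35), Nfil3, Aacs, which turns acetoacetate into a precursor for lipid synthesis (1.08 ± 0.17), and the transcription factor gene Irf4 (1.08 ± 0.24). The largest falls were Defb1, an antimicrobial peptide gene (-1.86 ± 0.32), Nr1d1, the nuclear RNA Malat1 (-1.39 ± 0.38), Lep, Ly6d (-1.37 ± 0.23), Dbp, the histone demethylase gene Kdm5a (-1.16 ± 0.29) and the protease gene Ctse (-1.13 ± 0.25). Of the other genes fixed in advance, Mest (-0.10 ± 0.12) and Sfrp5 (0.16 ± 0.20), both linked to growth of fat tissue, did not pass (adjusted p = 0.69 and 0.68).

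By camera with the preset correlation, 14 lists were called in this contrast, 12 higher and 2 lower, against 1 with an estimated correlation and 7 by permutation of the list means. The 7 were lipogenesis, cholesterol synthesis, NADPH and pentose phosphate, circadian clock, insulin and IGF signalling, TCA cycle and mast cells. With the run as a block camera called 16 lists, and 0 with an estimated correlation in limma. Permutation within runs passed 10 lists, the same 7 with adipocyte markers (adjusted p = 0.018), lipolysis and lipid droplets (0.026) and smooth muscle and pericytes (0.022). Some lists share genes and are not independent: adipocyte markers share several with lipolysis and lipid droplets, and Me1 is in both the lipogenesis and the NADPH list.

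**Figure D3:**
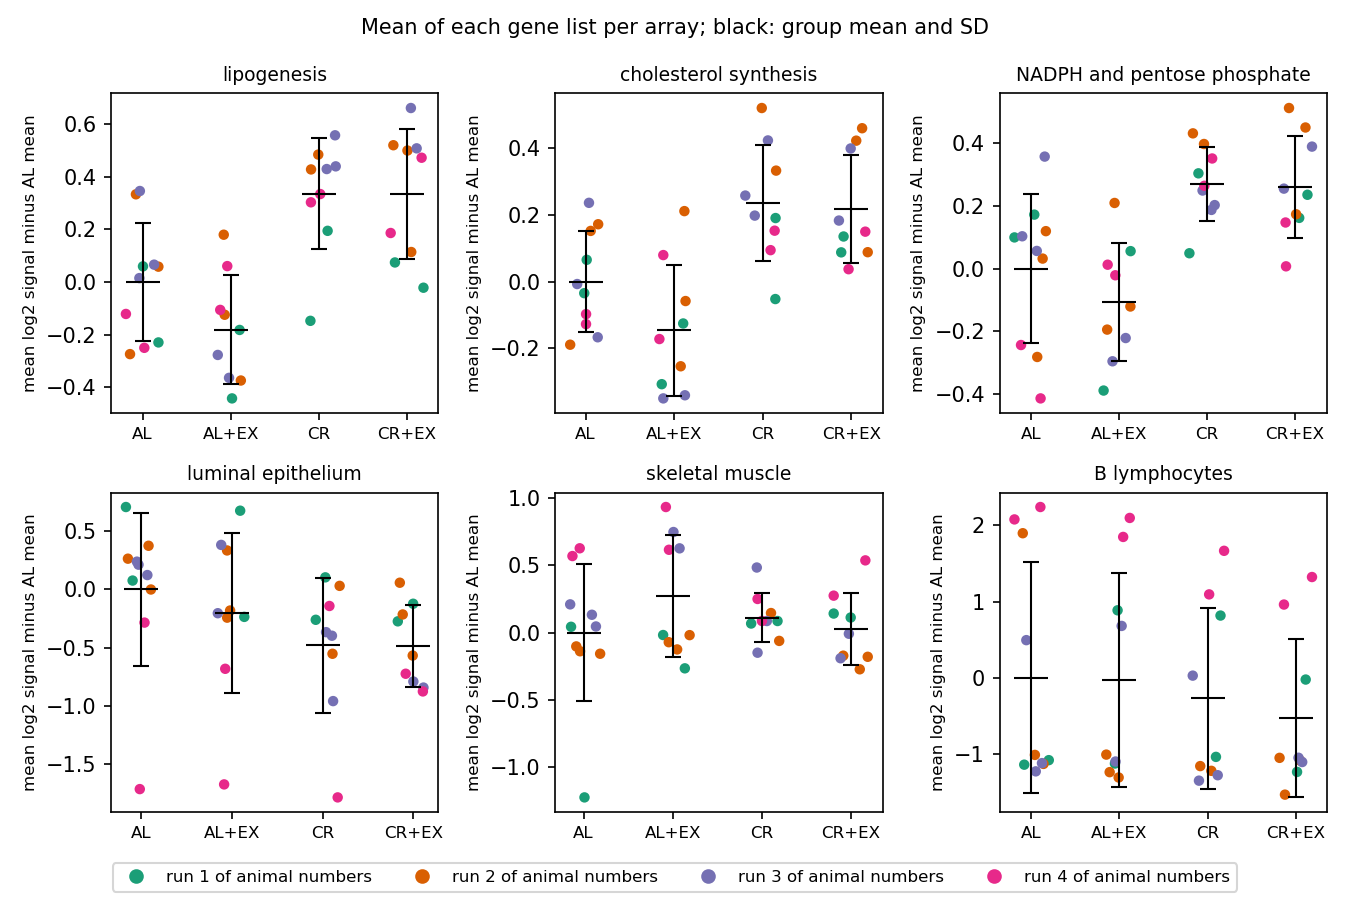
Mean log2 signal of 6 gene lists on each array minus the mean of the AL group, by group and coloured by run of animal numbers, with the group mean and SD in black. The 3 lipid and NADPH lists lie higher in CR and CR+EX than in AL and AL+EX, while B lymphocyte genes split every group into low and high arrays.

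CR against AL asks what restriction did in mice without a wheel (9 against 10 animals). The clock genes Nr1d1 (-1.81 ± 0.32) and Dbp (-1.40 ± 0.25) fell and Nfil3 rose by 1.24 ± 0.19 (adjusted p = 0.0027, 0.0027 and 0.00060). Elovl6 rose 1.82-fold, Me1 1.92-fold and Fdps 2.09-fold (adjusted p = 0.015, 0.017 and 0.046). Gpx8, a peroxidase of the endoplasmic reticulum, rose by 0.92 ± 0.14, Mgp, the matrix Gla protein gene, by 1.09 ± 0.24 and Mybph, of muscle myosin filaments, by 1.39 ± 0.32. Falls included Defb1 (-1.90 ± 0.45), Rest, a repressor of neuronal genes (-0.93 ± 0.16, with 1 of its 2 other probe sets in the same direction), and Rasd2 (-1.01 ± 0.23). Fewer than 80% of the settings kept the calls of Rasd2 (9 of 18), Defb1 (10 of 18), Fdps (11 of 18) and Mybph (13 of 18), which were lost in 12, 17, 18 and 15 of 37 fits without 1 array. Defb1 and Fdps were also lost with the mean of probe sets (adjusted p = 0.060 and 0.069). Lep was 3.72-fold lower but did not pass (-1.89 ± 0.54, adjusted p = 0.074).

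In that contrast 41 genes passed, 19 higher and 22 lower, all kept among 573 with the run as a block. The split was 10 higher and 4 lower of 14 after median centring. Lipogenesis had 2 of 20 genes higher and 4 adjusted over the list alone (adjusted p = 0.34 with an estimated correlation, exact permutation adjusted p = 0.055). Cholesterol synthesis had 2 of 19 and 4 (adjusted p = 0.42 with an estimated correlation, exact permutation adjusted p = 0.055). Of 13 lists called by camera, 0 held with an estimated correlation in limma and 0 by exact permutation, where 5 had an unadjusted p under 0.05. The run block gave 12, and 0 with an estimated correlation in limma. Luminal epithelium had a median of -0.44 with 0 of 24 genes past the threshold (adjusted p = 0.66 with an estimated correlation; 2 lower adjusted over the list alone). Leaving out a single array gave 9 to 150 genes. Without the arrays high in B lymphocyte genes or in the Gapdh ratio 9 and 10 genes passed. Collagens and matrix had a median of 0.14, and without the arrays high in B lymphocyte genes it was -0.14.

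CR+EX against AL+EX asks the same in mice with a wheel (9 against 9 animals). Hcar2 rose 3.00-fold (1.58 ± 0.37), Enpep 2.87-fold (1.52 ± 0.34), Aacs 2.42-fold (1.27 ± 0.25), Elovl6 2.23-fold (1.15 ± 0.18) and Fabp5, a fatty acid carrier, 2.20-fold (1.14 ± 0.26). The sterol genes Pmvk (0.96 ± 0.19) and Nsdhl (0.65 ± 0.13) rose, as did Taldo1 of the pentose phosphate pathway (0.52 ± 0.12) and Igf1 (0.74 ± 0.20, adjusted p = 0.046). Igf1 passed in only 9 of 18 settings and was lost in 19 of 37 fits without 1 array and with the mean of probe sets (adjusted p = 0.086). Nr1d1 (-1.66 ± 0.32), Defb1 (-1.81 ± 0.46), Ly6d (-1.46 ± 0.34), Dbp (-1.28 ± 0.25) and Ier3, an immediate early gene (-0.66 ± 0.12), fell. Lep was 1.85-fold lower without passing (-0.89 ± 0.55, adjusted p = 0.46).

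Here 153 genes passed, 79 higher and 74 lower, all kept among 558 with the run as a block, and the split was 85 and 22 of 107 after median centring. Lipogenesis had 5 of 20 higher and 10 adjusted over the list alone (median 0.37, adjusted p = 0.024 with an estimated correlation, exact permutation adjusted p = 0.014). Cholesterol synthesis had 2 of 19 higher and 8 adjusted over the list alone (median 0.32), and NADPH and pentose phosphate 2 of 9 and 4 (median 0.29), each with an adjusted p of 0.079 with an estimated correlation and an exact permutation adjusted p of 0.014. Camera called 9 lists, 1 held with an estimated correlation and 3 by exact permutation. With the run as a block camera called 11, and 0 with an estimated correlation in limma, where lipogenesis had an adjusted p of 0.051. Leaving out a single array gave 59 to 239 genes, and without the arrays high in B lymphocyte genes 59 passed.

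CR+EX against AL compares the combined regimen with the control (9 against 10 animals). Nfil3 rose by 1.35 ± 0.19 and Nr1d1 (-1.94 ± 0.32), Dbp (-1.43 ± 0.25) and Ly6d (-2.04 ± 0.33) fell. Igfals (1.53 ± 0.38), Enpep (1.42 ± 0.33), Gpnmb, a glycoprotein gene of macrophages and other cells (1.25 ± 0.30), Mgp (1.14 ± 0.24), the adhesion molecule gene Clmp (1.05 ± 0.24), Abca8a (0.88 ± 0.15) and Elovl6 (0.86 ± 0.17) rose, and Ctse fell by 1.49 ± 0.35. Under 80% of the settings kept Igfals (12 of 18), Gpnmb (12 of 17) and Ctse (13 of 18), which were lost in 11, 12 and 7 of 37 fits without 1 array. Ctse and Clmp were also lost with the mean of probe sets (adjusted p = 0.21 and 0.052). Lep (-1.87 ± 0.54, adjusted p = 0.088) and Igf1 (0.62 ± 0.20, adjusted p = 0.12) did not pass.

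In it 58 genes passed, 30 higher and 28 lower, all kept among 347 with the run as a block, with 26 higher and 9 lower of 35 after median centring. Lipogenesis had 2 of 20 higher and 4 adjusted over the list alone (adjusted p = 0.28 with an estimated correlation, exact permutation adjusted p = 0.12). Camera called 11 lists, of which 0 held with an estimated correlation in limma and 0 by exact permutation, where 6 had an unadjusted p under 0.05. The run block gave 15, and 0 with an estimated correlation in limma. Single arrays left out gave 26 to 105 genes, and 3 passed without the arrays high in B lymphocyte genes and 18 without those high in the Gapdh ratio. Collagens and matrix (median 0.13, adjusted p = 0.80 with an estimated correlation) had a median of -0.05 without the arrays high in B lymphocyte genes.

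CR against AL+EX sets restriction against the wheel (9 against 9 animals). Enpep (1.40 ± 0.34), H1f10 (1.45 ± 0.36), Hcar2 (1.37 ± 0.37), Aacs (1.28 ± 0.25), Me1 (1.20 ± 0.20), Elovl6 (1.16 ± 0.18), Fabp5 (1.10 ± 0.26) and Ltc4s, of leukotriene synthesis (1.24 ± 0.33), were higher under restriction. Defb1 (-1.89 ± 0.46), Nr1d1 (-1.53 ± 0.32), Rasd2 (-1.27 ± 0.24), Dbp (-1.26 ± 0.25) and Ccdc77 (-1.05 ± 0.26) were lower. Mgll, a lipase of fat breakdown (0.78 ± 0.21), and the heat shock gene Dnajb1 (0.43 ± 0.12) also passed, while Lep did not (-0.91 ± 0.55, adjusted p = 0.43). Mgll and Dnajb1 passed in 11 of 18 settings and Hcar2 in 14, and 12, 22 and 13 of 37 fits without 1 array lost them. Ltc4s was lost in 11 of these fits, and Mgll also with the mean of probe sets (adjusted p = 0.054).

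There were 183 genes past the threshold, 90 higher and 93 lower, all kept among 753 with the run as a block, and 74 higher and 16 lower of 90 after median centring. Lipogenesis had 5 of 20 higher and 10 adjusted over the list alone (median 0.44, adjusted p = 0.036 with an estimated correlation, exact permutation adjusted p = 0.0090). Cholesterol synthesis had 3 of 19 and 9 (median 0.37, adjusted p = 0.042 with an estimated correlation, exact permutation adjusted p = 0.013). NADPH and pentose phosphate had 3 of 9 and 4 (median 0.35, adjusted p = 0.060 with an estimated correlation, exact permutation adjusted p = 0.0090). Camera called 10 lists, 2 held with an estimated correlation and 3 by exact permutation. The run block also gave 10, and both calls with an estimated correlation were lost (adjusted p = 0.12 for each). Single arrays left out gave 56 to 295 genes, and 13 passed without the arrays high in B lymphocyte genes.

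AL+EX against AL asks what the wheel did in mice fed ad libitum (9 against 10 animals). No gene passed: limma called 0 genes, with 600 at an unadjusted p under 0.05 where 464.7 would be expected by chance. The smallest p-values belonged to Egln3, an oxygen-sensing hydroxylase gene (0.79 ± 0.20), the zinc finger gene Zfp617 (0.52 ± 0.12) and Sars, the seryl-tRNA synthetase gene (0.45 ± 0.11), each with an adjusted p of 0.44. Lep was at -0.98 ± 0.54 (adjusted p = 0.75).

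Camera called 8 lists there, and 0 held with an estimated correlation in limma or by exact permutation, where 2 had an unadjusted p under 0.05. The run block gave 11, and 0 with an estimated correlation in limma. Every one of the 21 skeletal muscle genes was above AL (median 0.27), with 0 past the threshold and 0 adjusted over the list alone (adjusted p = 0.99 with an estimated correlation, exact permutation p = 0.25 unadjusted). The list mean differed by 0.28 ± 0.14 with the run as a block, and permutation within runs gave an unadjusted p of 0.036 for this list, taken from 44. Without AL replicate 1 the difference was 0.15 ± 0.10 and p was 0.12. The smallest p was that of myoglobin, Mb (0.58 ± 0.26, adjusted p = 0.75). Lipolysis and lipid droplets had a median of -0.24 with 1 lower adjusted over the list alone (adjusted p = 0.99 with an estimated correlation, exact permutation adjusted p = 0.43), and lipogenesis had a median of -0.20 (adjusted p = 0.99 with an estimated correlation, exact permutation adjusted p = 0.94). The interferon response had a median of -0.26 and brown fat 0.31, each with an adjusted p of 0.99 with an estimated correlation. The respiratory chain (median 0.05, adjusted p = 0.99 with an estimated correlation) had a median of -0.03 without the arrays high in B lymphocyte genes.

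CR+EX against CR asks what the wheel added under restriction (9 against 9 animals). In limma 0 genes passed, with 83 at an unadjusted p under 0.05, and 0 of 44 lists were called by any of the 3 list tests, with 0 lists at an unadjusted permutation p under 0.05. Camera with the run as a block called 1 list, lost with an estimated correlation. The smallest p-values were those of Bmp6, a growth factor gene (0.30 ± 0.10), Cd300c2, a receptor gene of myeloid cells (-0.44 ± 0.15), and the zinc finger gene Zfp160 (0.51 ± 0.18), none of which passed. Igf1 was at 0.35 ± 0.20 and Lep at 0.03 ± 0.55.

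Averaged over diet, the wheel gave 0 genes in limma, with 266 at an unadjusted p under 0.05. The smallest p-values, none passing, belonged to Wdr77 (0.58 ± 0.15), Slc22a8, an organic anion transporter gene (-0.48 ± 0.13), and Tph1, of serotonin synthesis (0.71 ± 0.20). Camera called 6 lists: lipogenesis (median -0.09), cholesterol synthesis (-0.07), lipolysis and lipid droplets (-0.15), adipocyte markers (-0.13), interferon response (-0.14) and skeletal muscle (0.11). Each lost its call with an estimated correlation (adjusted p = 0.90 with an estimated correlation), and by permutation 0 lists passed and 0 had an unadjusted p under 0.05. The run block gave 10 lists, and 0 with an estimated correlation in limma.

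The interaction asks whether the wheel acted differently under restriction. In limma 0 genes passed, with 295 at an unadjusted p under 0.05, and the smallest adjusted p was 0.28, for Sars (-0.75 ± 0.16). The interaction for Lep was 1.01 ± 0.77 and did not pass. Camera called lipogenesis (median 0.24), brown fat (-0.28) and skeletal muscle (-0.38), and 0 held with an estimated correlation in limma (adjusted p = 0.98 with an estimated correlation) or by permutation (adjusted p = 0.96), with 0 lists at an unadjusted permutation p under 0.05. The run block gave 3 lists as well, and 0 with an estimated correlation in limma.

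Effects of restriction with and without a wheel, which share no arrays, correlated across genes at r = 0.55 (jackknife SE over arrays 0.16). The middle 95% of 100 simulated sets without effects ran from -0.47 to 0.43. Those sets shuffled residual arrays over the groups without regard to the run. Genes are not independent replicates, so no p is given. All 41 genes called in CR against AL had the same direction in CR+EX against AL+EX, 11 were called higher in both (0.16 expected if independent) and 5 lower in both (0.18 expected). Effects of the wheel with and without restriction correlated at -0.02 (SE 0.28), and averaged effects of restriction and the wheel at -0.07 (SE 0.27). Both lay inside the middle 95% of their simulated sets. CR against AL and AL+EX against AL correlated at 0.32 when sharing all AL arrays, and at 0.13 and -0.08 when each used its own set of AL arrays.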

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

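All tests of explanations in this part, and the splits of the samples, were chosen only after the results they measure had been seen.

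Lipid synthesis genes were higher under CR, with a difference in the mean of the lipogenesis list of 0.43 ± 0.07. A larger share of fat cells in restricted glands would raise adipocyte markers at least as much, if restriction itself left those markers unchanged. That condition was not tested. The adipocyte markers differed by 0.23 ± 0.09. The CR difference was larger for the lipogenesis mean than for the adipocyte mean by 0.19 ± 0.05 (permutation p within runs 0.00025). Under that condition this argues against fat cell share as the whole cause, though not as a part of it. Degraded RNA is argued against by a difference of 0.46 ± 0.08 without the 5 arrays with a high Gapdh ratio. The run of animal numbers is argued against by 0.43 ± 0.06 with the run as a block and by positive values in each run (0.22, 0.45, 0.62 and 0.43). The place of an animal within its run goes with its group, so these values cannot address it. A biological effect of restriction is consistent with these values and remains a hypothesis, and the hours between the last meal and collection, which the labels lack, stay open.

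Clock genes moved in opposite directions by phase: the mean of 10 day-phase genes fell by 0.50 ± 0.08 under CR and the mean of 4 genes of the opposite phase rose by 0.49 ± 0.09. The difference of the means was 0.98 ± 0.15, with a permutation p of 1e-05, the smallest that the 100000 draws can give. The genes were grouped by phase after their values had been seen and the p is against no effect of CR, so this describes the pattern. A shifted phase of the clock at collection predicts such a pattern and stays open. A differing share of lymphoid tissue is argued against, because the difference was 1.06 ± 0.12 with the B lymphocyte mean as a covariate. Whether groups were collected or fed at different hours cannot be told apart from an effect of restriction on the clock. The difference was positive in 4 of 4 runs, and the hours are not in the labels. The order of the groups by animal number was the same in each run, so the shared sign cannot settle this.

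Skeletal muscle genes were above AL in AL+EX (difference of the list mean 0.27 ± 0.18) and not in CR+EX against CR (-0.08 ± 0.18). Much of this rests on AL replicate 1, whose muscle mean of 12.28 was the lowest of all arrays: without it the difference was 0.13 ± 0.15 and the interaction -0.22 ± 0.21. Muscle tissue carried over in dissection is consistent with the median correlation of 0.73 between pairs of muscle genes within groups. Whether the spread between animals alone accounts for the pattern is not settled. The interaction on the list mean (-0.35 ± 0.25) had a permutation p of 0.16, and with the run as a block (-0.33 ± 0.19) permutation within runs gave 0.0496, not adjusted over the 44 lists. By run AL+EX exceeded AL by 0.45, 0.061, 0.56 and 0.18, with 0.28 ± 0.14 for the run block (permutation p within runs 0.036, unadjusted), and CR+EX minus CR was 0.050, -0.25, -0.24 and 0.24. Without AL replicate 1 the value of run 1 turned to -0.18, and the run block gave 0.15 ± 0.10 (permutation p within runs 0.12), with an interaction of -0.20 ± 0.14 (permutation p within runs 0.13). An effect of the wheel on the gland was not tested apart from these, so all explanations stay open.

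The list test gave a different effect of the wheel under restriction than without it for lipogenesis (median interaction 0.24, camera adjusted p = 0.016), brown fat (-0.28, adjusted p = 0.033) and skeletal muscle (-0.38, adjusted p = 1.8e-06). All 3 calls were lost with an estimated correlation (adjusted p = 0.98 with an estimated correlation).

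Among probe sets that name no gene or several genes, 108 of 1424 passed the threshold in the averaged CR contrast, 53 higher and 55 lower, against 103.7 expected if they were called as often as named probe sets.

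A value far from the rest of its group was looked for in 520 groups of arrays (83 genes, 44 lists and 3 array measures, each in 4 groups). It was found in 37, where chance gives about 1 in 20, or 26. Each value below is the gap to the nearest array divided by the range of the group. For genes on the low side the gaps were 0.57 for Kdm5a in CR replicate 7, 0.72 for Enpep and 0.51 for Wdr77 in CR replicate 8, 0.51 for Olfm1 in CR replicate 2, 0.52 for Me1 and 0.49 for G0s2 in CR replicate 1, and 0.58 for Aacs, 0.53 for Serpinh1 and 0.74 for Tsc22d3 in AL replicate 8. Also low were Wfdc2 (0.69) and Retn (0.52) in AL replicate 9, Wfdc2 in AL+EX replicate 8 (0.50), Bmp6 in AL+EX replicate 7 (0.62) and Slc22a8 in CR+EX replicate 3 (0.58). On the high side they were 0.53 for both Defb1 in CR replicate 9 (0.525) and Defb1 in CR+EX replicate 5 (0.534), 0.57 for Arntl in AL+EX replicate 8, 0.63 for Igfbp2 and 0.50 for Cma1 in CR replicate 9, and 0.61 for Atp5o in CR replicate 8.

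For list means, CR replicate 8 was high in fatty acid oxidation (0.61), TCA cycle (0.58), respiratory chain (0.60) and glycolysis (0.57). AL replicate 9 was low in luminal epithelium (0.59), basal epithelium (0.49) and hormone response (0.54). CR replicate 1 was low in lipolysis and lipid droplets (0.56) and high in the interferon response (0.76), and CR+EX replicate 5 was low in the TCA cycle (0.56). AL+EX replicate 8 was low in insulin and IGF signalling (0.50) and in antioxidant genes (0.64), AL+EX replicate 9 low in the circadian clock (0.53) and AL replicate 1 low in skeletal muscle (0.58). CR replicate 9 was high in collagens and matrix (0.55) and AL+EX replicate 4 in skin and hair (0.70). The Gapdh 3' to 5' ratio of AL replicate 2 was 7.03, with a gap of 0.69. With 7 of the 37 values CR replicate 8 had the most, and AL replicate 9 had 5.

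Chance is an unlikely source of the gene counts where restriction was compared. Of 100 splits of the same samples only 1, the real one, gave as many genes, and 1 is the lowest number possible. The highest other split gave 6 genes for CR against AL (41 real), 3 for CR+EX against AL (58), 43 for CR+EX against AL+EX (153), 89 for CR against AL+EX (183) and 294 for the averaged CR contrast (813). With the run as a block and splits within runs the result was again 1 of 100, with 573 real and 13 as the highest other for CR against AL, and 1743 and 243 for the averaged contrast. It was also 1 of 100 for CR+EX against AL (347 real, 54 as the highest other), CR+EX against AL+EX (558, 203) and CR against AL+EX (753, 173).

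With 0 genes called in limma for the wheel, any split gives at least as many, so that comparison of splits decides nothing. The highest other split gave 918 genes for AL+EX against AL, 14 for CR+EX against CR, 1016 for the averaged wheel contrast and 48 for the interaction. Chance cannot be excluded for the number of genes at an unadjusted p under 0.05 in limma: 45 of 100 splits gave at least the 600 genes of AL+EX against AL (highest other 2664), 98 the 83 of CR+EX against CR (1526), 75 the 266 of the averaged wheel contrast (2750) and 67 the 295 of the interaction (1357). Splits that call 918 or 1016 genes point to a structure of the samples, and the first component followed the B lymphocyte mean. Those splits ignore the run. By splits within runs, and the run as a block, chance could still not be excluded: 7 of 100 splits gave at least the 1004 genes at an unadjusted p under 0.05 of AL+EX against AL (highest other 1458), 21 the 307 of CR+EX against CR (699), 11 the 562 of the averaged wheel contrast (849) and 11 the 650 of the interaction (1066).

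Chance cannot be excluded for the number of lists called by camera with the preset correlation in the 8 contrasts with a called list, by splits that ignore the run. As many lists were called in 25 of 100 splits for CR against AL (13 real, 20 as the highest other), in 68 for AL+EX against AL (8, 18), in 20 for CR+EX against AL (11, 19) and in 52 for CR+EX against AL+EX (9, 22). The number was 64 for CR against AL+EX (10, 20), 22 for the averaged CR contrast (14, 21), 65 for the averaged wheel contrast (6, 23) and 93 for the interaction (3, 22). For CR+EX against CR 0 lists were called (highest other 22, with 0 lists at an unadjusted permutation p under 0.05), so any split gives at least as many and the comparison decides nothing. Within runs and with the run as a block, the averaged CR contrast had the lowest number, with 4 of 100 splits giving as many lists (16 real, 20 as the highest other). It is 1 of 9 contrasts and no adjustment was made for the 9, so chance is not excluded there either. As many were called in 46 splits for CR against AL (12, 22), 37 for AL+EX against AL (11, 19), 15 for CR+EX against AL (15, 18), 100 for CR+EX against CR (1, 21) and 24 for CR+EX against AL+EX (11, 16). The numbers were 55 for CR against AL+EX (10, 24), 40 for the averaged wheel contrast (10, 21) and 89 for the interaction (3, 21).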

How the results depend on the processing

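The settings were planned, except for the permutation of list means, also within runs, and 3 fits, all chosen only after the data were seen. The 3 fits were the run block with the B lymphocyte covariate, and those without the arrays high in B lymphocyte genes or in the Gapdh ratio. No paired analysis was possible because the labels give animal numbers and no replicate numbers that link animals across groups. The 4 runs of animal numbers, each with all 4 groups, served as a block instead. Of 155 results for named genes past the threshold, none changed direction under any setting in which it was tested, and 87 passed in every fit that left out 1 array. The settings refit the same arrays, or most of them, for genes already chosen by their adjusted p, so a kept direction is weak evidence. Single other probe sets of a gene were not among these settings, and some moved the opposite way. With the run as a block all 155 passed and without the arrays high in B lymphocyte genes 63. The counts of 0 genes stayed 0 for AL+EX against AL and CR+EX against CR under every setting. Dim genes, below a signal of 88.7, were not tested except without the filter. For changes below the cause was not tested, unless the setting by itself leaves fewer genes or arrays.

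Counts that moved by over 1.5 times were, for CR against AL (41 genes), 24 with quantile normalization, 14 with median centring, 19 without the filter, 69 without the dimmer 50% of genes, 17 without the variance trend, 175 with array weights, 63 with only the groups compared and 573 with the run as a block. With a list mean as a covariate they were 155 (skeletal muscle), 193 (B lymphocytes) and 171 (brown fat). For CR+EX against AL (58 genes) they were 35 with median centring, 1.4e+02 with array weights (2 digits), 347 with the run as a block, and 172, 129, 172 and 174 with the skeletal muscle, B lymphocyte, luminal and brown fat covariates. For CR+EX against AL+EX (153 genes) they were 88 with only the groups compared, 558 with the run as a block, 92 with the skeletal muscle and 314 with the luminal covariate. For CR against AL+EX (183 genes) they were 90 with median centring, 753 with the run as a block and 282 with the B lymphocyte covariate. The averaged CR contrast (813 genes) gave 1743 with the run as a block and 1240 probe sets when every probe set was tested. The interaction gave 1 gene with the brown fat covariate, against 0.

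The added settings gave, in the order CR against AL, CR+EX against AL, CR+EX against AL+EX, CR against AL+EX and averaged CR, 561, 204, 395, 701 and 1347 genes with the run block and B lymphocyte covariate, and 9, 3, 59, 13 and 497 without the arrays high in B lymphocyte genes, a fit with fewer arrays. The first of them also gave 1 gene for the averaged wheel contrast. Without the arrays with a high Gapdh ratio there were 10 genes for CR against AL and 18 for CR+EX against AL.

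Lists called with an estimated correlation numbered 0 for CR against AL (13 with the preset value), 0 for AL+EX against AL (8), 0 for CR+EX against AL (11), 1 for CR+EX against AL+EX (9), 2 for CR against AL+EX (10), 1 for averaged CR (14), 0 for the averaged wheel (6) and 0 for the interaction (3). With the run as a block and an estimated correlation 0 lists were called in limma in any contrast, so the calls in those 3 contrasts were lost. By permutation of the list means 0, 0, 0, 3, 3, 7, 0 and 0 passed, with 5, 2, 6, 9, 7, 10, 0 and 0 at an unadjusted p under 0.05, and permutation within runs gave 10 lists for averaged CR. For CR+EX against CR 1 list was called with median centring, without the filter, with the run block, with the run block and B lymphocyte covariate and without the arrays high in B lymphocyte genes, and 3 without those with a high Gapdh ratio. The averaged wheel contrast gave 10 lists with the run block, the skeletal muscle or the brown fat covariate, 12 with the luminal covariate and 11 with the run block and B lymphocyte covariate. The interaction gave 1 with the skeletal muscle covariate, 12 without the arrays high in B lymphocyte genes and 6 without those with a high Gapdh ratio. Without the arrays high in B lymphocyte genes, CR+EX against AL gave 6 lists and averaged CR 9.

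In 12 cases a list changed direction in the camera test, which sets its members against all other genes. Its median, given here, changed sign in 9 of them and moved near 0 without changing sign in 3: skeletal muscle in the interaction and the averaged wheel contrast, and luminal epithelium in CR+EX against AL. With the skeletal muscle covariate these were the respiratory chain in AL+EX against AL (-0.045), and skeletal muscle itself in CR+EX against AL+EX (0.017) and the interaction (-0.018). With the luminal covariate they were fatty acid oxidation in CR against AL (-0.096) and luminal epithelium itself in CR against AL (0.027), CR+EX against AL (-0.014) and averaged CR (0.050). With the brown fat covariate it was brown fat itself in AL+EX against AL (-0.042). Without the arrays high in B lymphocyte genes they were collagens and matrix in CR against AL (-0.14) and CR+EX against AL (-0.052), the respiratory chain in AL+EX against AL (-0.033) and skeletal muscle in the averaged wheel contrast (0.0068). A covariate made of a list removes that list's own difference by construction.

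Leaving out 1 array at a time gave 9 to 150 genes for CR against AL, 26 to 105 for CR+EX against AL, 59 to 239 for CR+EX against AL+EX, 56 to 295 for CR against AL+EX and 611 to 960 for averaged CR, and 0 in limma for the other contrasts. In CR against AL the count moved by over 1.5 times without AL replicate 3 (26), 4 (24), 5 (82), 6 (24), 7 (10) or 8 (13), AL+EX replicate 4 (16), 6 (68), 7 (72) or 8 (65), CR replicate 1 (150), 2 (21), 4 (10), 5 (9), 6 (11), 7 (10), 8 (16) or 9 (16), and CR+EX replicate 1 (21), 4 (23) or 6 (21). In CR+EX against AL it moved without AL replicate 3 (34) and CR+EX replicate 3 (30), 4 (37), 5 (105) or 6 (26). In CR+EX against AL+EX it moved without AL+EX replicate 5 (239), 6 (67) or 7 (60) and CR+EX replicate 3 (65), 4 (59), 6 (72) or 7 (68). In CR against AL+EX it moved without AL+EX replicate 2 (110), 4 (120), 6 (56) or 7 (62) and CR replicate 1 (295), 3 (118), 4 (112), 5 (93), 6 (100), 7 (86) or 8 (101).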

Other observations

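The test of a lymph node in this part was chosen only after the lymphoid arrays had been seen, and its criterion was settled after a first version over all 37 arrays had been run, in which genes of red blood cells also followed the B lymphocyte mean.

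The glands differed most in their lymphoid genes. B lymphocyte genes averaged 9.79 on the log2 scale in the fourth run of animal numbers (SD 0.49, n = 8) and 7.23 to 7.64 in the other runs, and T lymphocyte genes averaged 9.04 in the fourth run and 6.69 to 7.12 in the others. Luminal epithelium genes were lower in the fourth run, at 8.67, than in the others, at 9.40 to 9.74. Brown fat genes averaged 10.9, 10.4, 10.4 and 11.2 in runs 1 to 4.

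A lymph node in the dissected tissue is a candidate source of the lymphoid signal. Over the 15 arrays above the gap, the mean of 3 genes of lymph node stroma (Cxcl13, Glycam1 and Madcam1) rose with the B lymphocyte mean: Spearman's rho was 0.91 and Pearson's r 0.91 (permutation p = 2e-05 for each, adjusted p = 8e-05 over 4 relations). Pearson's r was 0.89 without the 2 arrays farthest from the median, 0.76 in the fourth run (n = 8) and 0.93 in the other runs (n = 7). Red blood cell genes gave rho = 0.42 and r = 0.33 over the same arrays (permutation p = 0.12 and 0.23, adjusted p = 0.20 and 0.30). Below the gap the stroma genes gave rho = 0.32 and r = 0.35 (permutation p = 0.15 and 0.11, adjusted p = 0.20 and 0.22). The list has 7 members named on the array, of which 3 are left out here as too dim (Clca1, Ltb and Fcrla) and 1 as a B lymphocyte gene (Cr2). With the 3 dim genes added, rho was 0.98 and r 0.96 above the gap (permutation p = 1e-05 for each, the smallest that the draws can give), and 0.30 and 0.24 below it (permutation p = 0.18 and 0.28). Whether Ltb and Fcrla are expressed by the lymphocytes themselves was not tested, so the values with the dim genes add no weight for a lymph node. Glycam1 is also a gene of milk secretion, so it is not specific to a lymph node.

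The Gapdh 3' to 5' ratio was above 2 on 5 arrays, 3 of AL and 2 of CR+EX. Of these, 4 belonged to run 1 and 1 to run 3. The highest signal of an array averaged 24720, 27300, 45667 and 53439 in runs 1 to 4.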
